A study of Homo sapiens with 9 samples.

How the data were processed

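Immunoprecipitated DNA was measured in 8 libraries, 1 per group, and 1 further sample, input DNA, was not analysed here. Per the labels' protocols, sonicated genomic DNA was captured with an antibody to 5hmC and sequenced as single-end reads. The labels describe the tissue and urine libraries as pools and the cell line libraries as stable shRNA lines. Per the submitters' processing notes, Bowtie 1.1.2, SAMtools 1.3.1, Picard 2.4.1, MACS2 and DiffBind were used with genome build hg19. The version and settings of MACS2, and what DiffBind was used for, were not given in the sources used here.

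Each library had 1 list of peaks, and whether a library pooled several captures was not given in the sources used here. The fold enrichment of each peak over its background, a ratio, was calculated by the authors' peak caller. The deposited lists also give -log10 p and -log10 q values per peak, and a score that equals the whole part of 10 times the -log10 q. These values are the authors', and they were used only to describe, rank or filter peaks within a list. The highest q in any list was between 0.0315 and 0.0492.

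Depth was inferred from the fold values. MACS2 calculates a fold as the fragments over the summit plus 1, divided by the background plus 1, so that folds at the library-wide background fall on a grid of equal steps. Between 23.3% and 37.4% of the folds of a library lay on that grid, within 1e-05 per step. The step gave the background per position, and dividing by the commonest peak width, which equals the shortest, gave 1.48 fragments per kb in every library. The fragments over a summit follow from the fold and the step and are a lower bound where the local background was higher. Neither the depth nor the fragments were given in the sources used here.

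Peaks on chromosomes 1 to 22 were compared as deposited, and a peak counted as shared when at least 1 bp overlapped a peak of the other list. Shares have exact Clopper-Pearson 95% intervals, and ratios of shares have exact intervals given the sum of both counts. These cover counting error only, since capture and amplification are not part of them and peaks are not independent of each other. With 1 library per group no test was run and no p-value is given. Chance overlap was measured by shifting the other list by a random distance around each chromosome, 100 times per pair of lists and 20 times per subset of peaks. A chromosome was split into arms at the widest gap between the peaks of all libraries together. This gap did not mark the centromere on chromosome 6 and was not usable on chromosomes 13, 14, 15, 21 and 22, which were kept whole, a choice made after the data were examined. Peak summits were counted in windows of 1 Mb with at least 20 peaks in both libraries together. The scaled log2 ratio of a window is the log2 ratio of peak counts plus a pseudocount of 1, minus the log2 ratio of the list lengths. Counting noise was simulated 100 times by dividing the peaks of each window at random in proportion to the list lengths. This treats the lists as independent and overstates the noise where they share peaks.

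No hg19 genome or annotation was used here, so peaks are given by position and not by gene. The genomic context of peaks, the fixed gene lists and the cell type markers planned before the data were examined were therefore not analysed here. The rule fixed beforehand for that case named, for each comparison, the 5 peaks per library with the highest fold among those absent from the other library, and the 5 highest and 5 lowest windows. The leading ones are given in the text. Numbers of protein-coding genes per chromosome came from a RefSeq table on GRCh38, of which no coordinate was used. Chromosomes X and Y were left out of every comparison, with X added in 1 alternative.

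Alternatives fixed before the data were examined were a -log10 q of at least 5, the same number of strongest peaks in each list, at least 50% of a peak covered by a peak of the other list, peaks widened by 500 bp on each side, and covered bases in place of peaks for 3p. Added after the data were examined were peaks with 16 or more summit fragments, normal urine in place of NAT tissue, the ratio of 3p to 3q within a library, RCC tissue peaks without the NAT library, and the difference between the urine pools.

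Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The overlap of RCC tissue with NAT tissue was checked against bedtools, which gave the same 9314 peaks at 1 bp and 8518 at 50% of the length. Tested on simulated data, 97.5% of 200 windows changed 4-fold were found beyond 2-fold, as were 1.72% of the unchanged windows, among 2000 windows of 25 peaks.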

Results

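The genome-wide distribution of 5-hydroxymethylcytosine (5hmC), the oxidation product of 5-methylcytosine made by TET enzymes, was profiled in clear cell renal cell carcinoma (RCC) by antibody capture and sequencing. There were 8 peak lists, with 1 library in each group. A pair came from tissue pools, RCC tissue and normal adjacent tissue (NAT). Another pair came from urine pools of RCC patients and of normal donors. The remaining 4 lists came from the RCC cell lines Caki-1, which has wild-type VHL, and Caki-2, which lacks VHL, each with a control shRNA or a stable shRNA against SUV39H1, an enzyme that trimethylates histone H3 at lysine 9 (H3K9me3). Autosomal peaks numbered 56305 in RCC tissue, 46231 in NAT tissue, 60665 in RCC urine and 66605 in normal urine. The cell line lists were shorter, with 31407 peaks in Caki-1 control, 25893 in Caki-1 knockdown, 32336 in Caki-2 control and 25596 in Caki-2 knockdown. The fold values of the lists placed the background at 1.48 fragments per kb in each of the 8 libraries. Equal backgrounds per kb correspond to equal read numbers, so the lists were compared at equal inferred depth. With 1 library per group no difference has a replicate check, no test was run, and the 95% exact intervals given below cover counting error only.

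A core of strong 5hmC peaks was found in every library, and NAT tissue stood apart in the rest. Peaks overlapping a peak of all 7 other libraries numbered from 3437 in Caki-1 control to 3567 in Caki-2 knockdown. The median fold enrichment of this core ran from 8.503 in NAT tissue, against 5.71 for its peaks found in no other library, to 15.4 in RCC tissue, against 4.86. Peaks found in no other library made up 74.1% of the NAT tissue list (95% interval 73.7 to 74.5%), compared with 27.6% in RCC tissue, 31.3% in RCC urine, 33.7% in normal urine and 13.5 to 16.01% in the cell lines. The RCC tissue list overlapped the normal urine list (50.7% of its peaks) and the RCC urine list (47.5%) far more than the NAT tissue list (16.5%).

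**Figure D1:**
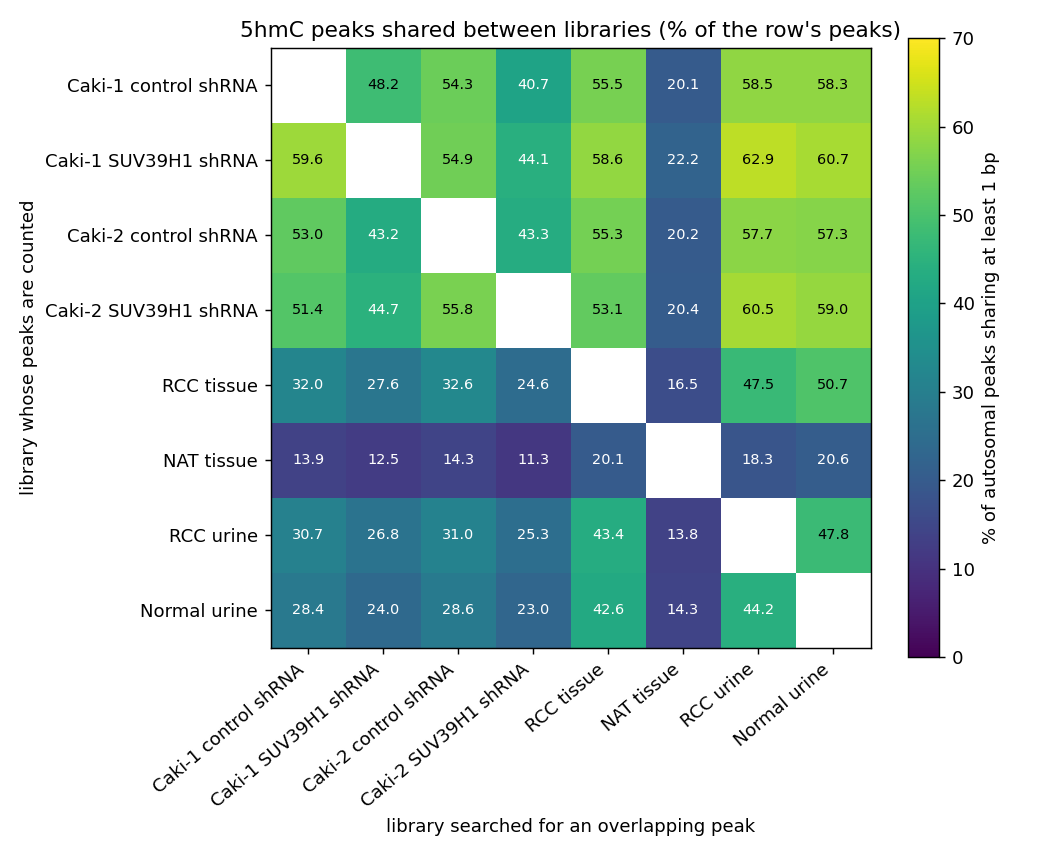
Percentage of each library's autosomal 5hmC peaks (rows) that share at least 1 bp with a peak of another library (columns), with 1 library per group. The NAT tissue row runs from 11.3 to 20.6%, and RCC tissue peaks were found in NAT tissue in 16.5% of cases against 50.7% in normal urine.

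The tissue pair addressed how 5hmC differs between RCC and adjacent kidney. NAT tissue carried far more peaks at chromosome ends and on chromosomes 19, 17 and 22, while RCC tissue carried more on 4q, 5q, 1q and 3q. Chromosome arm 19p held 4.86% of NAT peaks and 1.51% of RCC peaks, an RCC to NAT ratio of 0.311 (95% interval 0.287 to 0.337). The ratio was 0.515 for 17p, 0.529 for 17q and 0.534 for chromosome 22, and it reached 2.39 (95% interval 2.21 to 2.60) for 4q, 2.19 for 5q, 2.01 for 1q and 1.84 for 3q. Against normal urine RCC tissue was at 1.33 on 4q, 1.38 on 5q, 1.16 on 1q and 1.01 (95% interval 0.952 to 1.078) on 3q, and NAT tissue at 0.555, 0.629, 0.579 and 0.552. With this reference NAT tissue lay farther from 1 than RCC tissue on each of these arms. Which tissue changed cannot be decided, since the shares of a list depend on each other and normal urine is 1 pool of other DNA. Chromosomes 19, 17 and 22 are the densest in protein-coding genes, with 24.7, 14.4 and 13.1 genes per Mb spanned by peaks. Over all 22 chromosomes the Spearman correlation of gene density with the NAT to RCC ratio was 0.6002, and 0.540 without chromosome 19. With peaks per Mb of a single library it was 0.641 in NAT tissue and 0.508 in RCC tissue, both below RCC urine (0.851) and normal urine (0.849). In rank order the NAT list was therefore not unusual in following gene density, but it held larger shares on the densest chromosomes. NAT tissue over normal urine was at 2.64 on 19p, 1.09 on 19q, 1.45 on 17p, 1.52 on 17q and 1.64 on chromosome 22. Chromosome 21, with 6.19 genes per Mb, had a NAT to RCC ratio of 1.61, and chromosome 1, with 8.29, one of 0.808. Peaks within 5 Mb of a chromosome end made up 40.6% of the NAT list (95% interval 40.2 to 41.1%) and 10.9% of the RCC list (95% interval 10.6 to 11.1%).

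Of the RCC tissue peaks, 46991 (83.5%, 95% interval 83.1 to 83.8%) overlapped no NAT peak, and of the NAT tissue peaks 36926 (79.9%, 95% interval 79.5 to 80.2%) overlapped no RCC peak. Randomly shifted NAT peaks overlapped 1.23% of RCC peaks on average, against 16.5% observed, and the covered bases had a Jaccard index of 10.9%. The 5 RCC tissue peaks absent from NAT tissue that had the highest fold enrichment were each found in all 6 libraries other than NAT tissue. The strongest lay on chromosome 5 at 171340676 to 171341049 (fold 31.0), followed by chromosome 1 at 245961498 to 245961920 (fold 27.9). The strongest NAT tissue peak absent from RCC tissue lay on chromosome 8 at 12417423 to 12418030 (fold 20.002) and was found in no other library. The same held for those on chromosome 7 at 159609 to 160174 (fold 17.3) and chromosome 4 at 52800 to 54329 (fold 15.1). That on chromosome 19 at 3381457 to 3382356 (fold 16.4) was found in 2 other libraries. Among RCC peaks with 16 or more summit fragments, a group chosen after the data were examined, 12.4% were absent from NAT tissue (95% interval 11.2 to 13.6%).

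In 1 Mb windows the 5 lowest RCC to NAT ratios all lay close to chromosome ends. The window at 139 to 140 Mb of chromosome 9 held 13 RCC and 273 NAT peaks, a log2 ratio scaled to the list lengths of -4.58. Windows at 0 to 1 Mb and 1 to 2 Mb of chromosome 16 had scaled log2 ratios of -4.07 and -4.05, that at 0 to 1 Mb of chromosome 11 had -3.76, and that at 80 to 81 Mb of chromosome 17 had -3.54. The highest ratios lay in windows with few peaks, among them 172 to 173 Mb of chromosome 1 with 21 RCC peaks and 0 NAT peaks, and 86 to 87 Mb of chromosome 12 and 63 to 64 Mb of chromosome 16, each with 23 RCC peaks and 1 NAT peak. The standard deviation of the log2 ratio over 2080 windows was 1.19, against 0.49 from counting noise alone.

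Loss of 3p, which carries VHL, is the common lesion of clear cell RCC, and 5q gain and 14q loss were named beforehand with it. The 3p share of peaks was higher in RCC than in NAT tissue, 2.15% against 1.57%, a ratio of 1.37 (95% interval 1.25 to 1.51). This direction turned when normal urine took the place of NAT tissue, an alternative chosen after the data were examined, with a ratio of 0.742 (95% interval 0.690 to 0.798), the lowest of the 38 arms and whole chromosomes in that comparison. NAT tissue lay lower still on 3p against normal urine, at 0.541 (95% interval 0.496 to 0.589), but it was about as low on 3q, at 0.552. RCC tissue was at 1.01 on 3q. A low 3p share against urine was thus found in both tissues, but one low relative to 3q only in RCC tissue of the pair. Within chromosome 3, 3p held 38.9% of the peaks in RCC tissue (95% interval 37.2 to 40.7%), 46.1% in NAT tissue (95% interval 43.6 to 48.6%), 45.5% in RCC urine and 46.5% in normal urine. The RCC cell lines lay lower still, at 21.3% in Caki-1 control, 19.1% in Caki-1 knockdown, 27.8% in Caki-2 control and 17.6% in Caki-2 knockdown. The share on 5q was higher in RCC tissue against both references, by 2.19 times against NAT tissue and 1.38 times (95% interval 1.309 to 1.457) against normal urine, where it was the highest of all arms. Chromosome 14 showed a ratio of 1.03 (95% interval 0.955 to 1.105) against NAT tissue and 0.919 (95% interval 0.861 to 0.981) against normal urine.

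**Figure D2:**
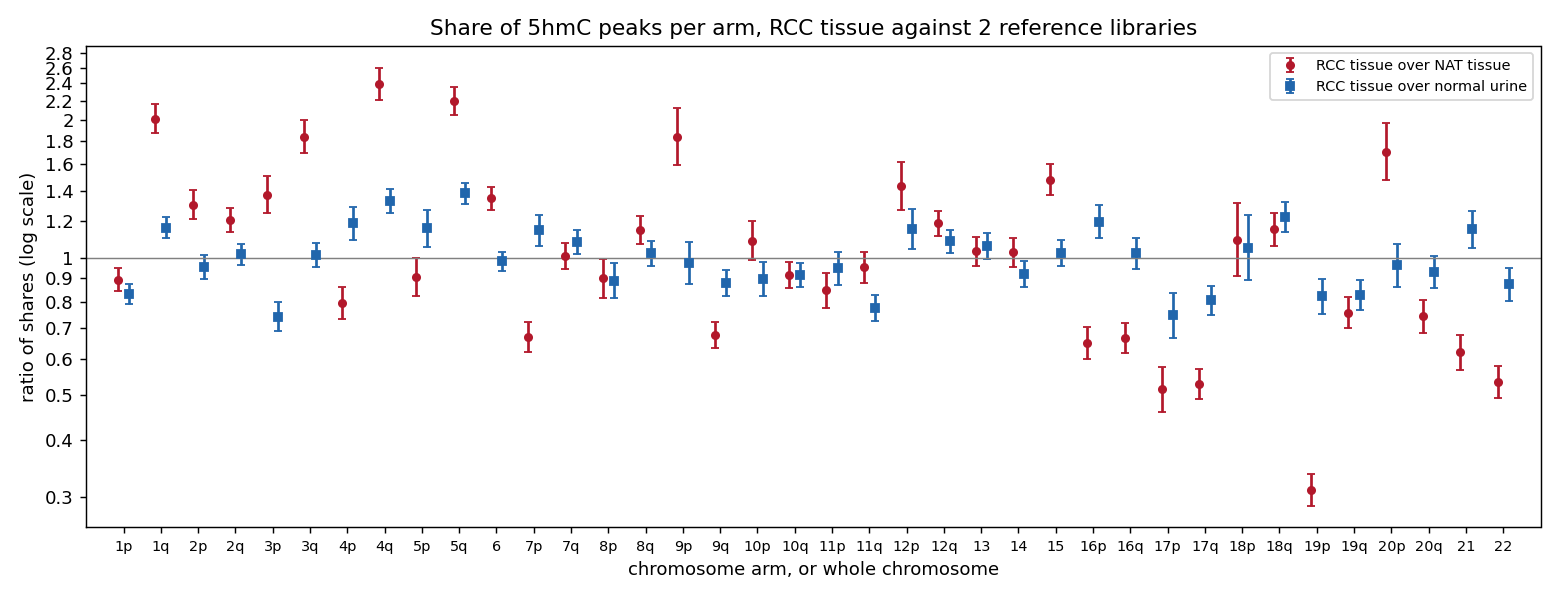
Ratio of the share of autosomal 5hmC peaks on each arm or whole chromosome (log axis) in RCC tissue over NAT tissue (red circles) and over normal urine (blue squares), with 95% exact intervals for counting error and 1 library per group. Chromosome 3p lies at 1.37 against NAT tissue and 0.742 against normal urine, and 5q lies above 1 against both.

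The urine pair addressed whether 5hmC in DNA from urine differs with RCC. The urine pools had similar shares of 5hmC peaks on each chromosome arm. Across the arms and whole chromosomes the ratio of RCC to normal urine ran from 0.880 on 17p to 1.09 on 4q, and on 3p it was 1.03 (95% interval 0.968 to 1.101). Of the 38 arms and whole chromosomes, 5 were higher and 6 lower in RCC urine beyond their counting intervals. In 2459 windows of 1 Mb the standard deviation of the log2 ratio was 0.37, against 0.43 from simulated counting, and 24 windows were beyond 2-fold up and 6 down, with 31.9 and 33.5 from counting. The simulation overstates the noise of lists that share peaks, so no regional difference is excluded by it. The lowest window, at 39 to 40 Mb of chromosome 10, held 16 peaks in RCC urine and 72 in normal urine (scaled log2 ratio -1.97), and that at 10 to 11 Mb of chromosome 21 held 14 and 47 (-1.54). The highest was at 61 to 62 Mb of chromosome 12, with 18 and 6 peaks (1.58). The windows on chromosomes 10 and 21 lie by the widest gap between peaks of their chromosome, which starts at 39155034 and 11186828. All peaks of the window on chromosome 10 thus lay at its start, before the gap, so it is not an ordinary region of 1 Mb.

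Single peaks nevertheless differed in large numbers. In RCC urine 52.2% of peaks (95% interval 51.8 to 52.6%) overlapped no normal urine peak, and in normal urine 55.8% (95% interval 55.5 to 56.2%) overlapped no RCC urine peak, with 1.40% and 1.27% overlap for shifted peaks. Nearly all unshared peaks were weak. Absence from normal urine fell from 60.9% of RCC urine peaks with 5 or 6 summit fragments to 22.7% with 9 to 11, 7.09% with 12 to 15 and 0.266% (95% interval 0.107 to 0.547%) with 16 or more. The strongest peak of RCC urine absent from normal urine lay on chromosome 9 at 125404218 to 125404600 (fold 14.6), and the strongest of normal urine absent from RCC urine on chromosome 10 at 100272400 to 100272715 (fold 18.3).

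**Figure D3:**
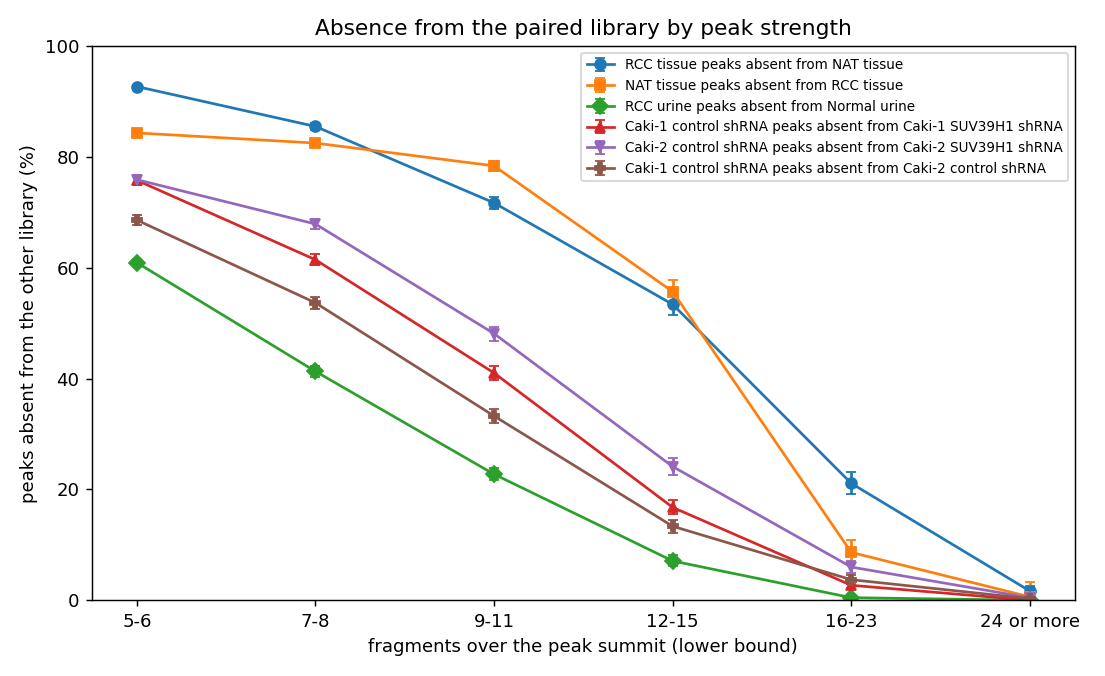
Percentage of peaks absent from the paired library (vertical axis) by the lower bound on fragments over the peak summit (horizontal axis), with 95% exact intervals for counting error and 1 library per group. Absence falls with strength in every pair, from 60.9% to 0.464% between 5 to 6 and 16 to 23 fragments for RCC against normal urine, and stays highest between the tissues.

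RCC tissue peaks that NAT tissue lacked were found in both urine pools, and no more often in RCC urine. Of the 46991 such peaks, 41.4% (95% interval 40.9 to 41.8%) overlapped an RCC urine peak and 44.1% (95% interval 43.6 to 44.5%) a normal urine peak, a difference of -2.73 percentage points (95% interval -3.23 to -2.22). NAT tissue peaks that RCC tissue lacked were nearly missing from urine, with 3.12% in RCC urine and 4.58% in normal urine, against 1.62% and 1.80% for shifted urine peaks. Peaks shared by both tissues were found in 78.7% and 84.3% of cases. Peaks of RCC tissue and RCC urine that were missing from both NAT tissue and normal urine numbered 6643, and the mirror set, in RCC tissue and normal urine but in neither NAT tissue nor RCC urine, numbered 7925. With the same number of strongest peaks from all 4 lists, the RCC minus normal difference between the urine pools narrowed to -0.476 percentage points (95% interval -1.04 to 0.0889), and with a -log10 q of at least 5 it widened to -5.72 (95% interval -6.45 to -4.99).

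The RCC cell lines resembled RCC tissue far more than NAT tissue, but so did both urine pools. RCC urine peaks were found in RCC tissue in 43.4% and in NAT tissue in 13.8% of cases, and normal urine peaks in 42.6% and 14.3%. The contrast is thus not particular to RCC cells. Of the RCC tissue peaks 42.3% (95% interval 41.9 to 42.7%) overlapped a peak of either control line, 32.0% in Caki-1 and 32.6% in Caki-2, whereas 13.9% and 14.3% of NAT tissue peaks did. Read from the lines, 55.5% of Caki-1 control peaks and 55.3% of Caki-2 control peaks were found in RCC tissue, 20.1% and 20.2% in NAT tissue, and 58.3% and 57.3% in normal urine. RCC tissue peaks missing from NAT tissue were found in either line in 35.9% of cases and NAT tissue peaks missing from RCC tissue in 2.28%. Peaks in RCC tissue and RCC urine but in neither reference were found in either line in 39.4% of cases, and the mirror set with normal urine in 34.0%.

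The control lines, which differ in VHL and in much else, differed by whole chromosome regions. DNA copy number was not measured here, so differences in 5hmC cannot be told apart from differences in copy number between the lines. Caki-1 had the larger share of peaks on 16q (ratio 2.31, 95% interval 2.07 to 2.59), 9p (2.05), 1q (2.03) and 8q (1.76). Caki-2 had the larger share on 19q (ratio 0.316, 95% interval 0.283 to 0.352), 20p (0.349), chromosome 6 (0.371) and 12q (0.462). The 5 windows with the lowest Caki-1 to Caki-2 ratio included 4 on 12q. The window at 82 to 83 Mb of chromosome 12 held 1 peak in Caki-1 and 114 in Caki-2 (scaled log2 ratio -5.80), that at 84 to 85 Mb held 2 and 79 (-4.69), and that at 83 to 84 Mb held 5 and 90 (-3.88). On chromosome 19, the window at 22 to 23 Mb held 0 peaks in Caki-1 and 34 in Caki-2. In the other direction, 60 to 61 Mb of chromosome 16 held 22 peaks in Caki-1 and 0 in Caki-2. Of the 5 strongest Caki-2 peaks absent from Caki-1, 4 lay on chromosome 12, led by 82951029 to 82951440 (fold 26.6).

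At the level of single peaks, 45.7% of Caki-1 control peaks (95% interval 45.2 to 46.3%) overlapped no Caki-2 control peak, and 47.0% of Caki-2 peaks (95% interval 46.4 to 47.5%) overlapped no Caki-1 peak. Shifted Caki-2 peaks overlapped 0.910% of Caki-1 peaks. Among Caki-1 peaks with 16 or more summit fragments, 2.55% (95% interval 2.02 to 3.16%) were absent from Caki-2. The standard deviation of the window log2 ratio was 0.94, against 0.49 from counting noise.

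Knockdown of SUV39H1 was used to relate H3K9me3 to 5hmC. The level of SUV39H1 itself was not measured by these lists, so the knockdown could not be checked. In Caki-1 the list after knockdown was shorter by 5514 peaks, chromosome 10 took a larger share and 2q a smaller one. Peaks on 10p rose from 1.88% to 2.83% of the list (ratio 1.51, 95% interval 1.35 to 1.68) and those on 10q from 3.21% to 4.80% (ratio 1.50, 95% interval 1.38 to 1.63). Chromosome 15 had a ratio of 1.33 and 1q one of 1.19. On 2q the share fell from 6.13% to 3.93% (ratio 0.641, 95% interval 0.593 to 0.692). The window with the highest scaled log2 ratio (2.22) was 10 to 11 Mb of chromosome 21, with 12 peaks in the control and 49 after knockdown. The 5 lowest windows included 4 on 2q, at 203 to 204 Mb with 18 and 4 peaks (-1.65), at 217 to 218 Mb with 25 and 8 (-1.25), at 219 to 220 Mb with 22 and 7 (-1.25) and at 206 to 207 Mb with 16 and 5 (-1.22). They are extremes picked from 1094 windows. At 206 to 207 Mb the counting interval of the ratio of shares, 0.109 to 1.083, included 1.

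Of the Caki-1 control peaks, 51.8% (95% interval 51.3 to 52.4%) were absent after knockdown, and 40.4% of the knockdown peaks (95% interval 39.8 to 41.0%) were absent from the control. Among control peaks with 16 or more summit fragments, 1.78% (95% interval 1.35 to 2.31%) were absent. The strongest of the absent peaks lay on chromosome 9 at 136719009 to 136719547 (fold 16.9) and on chromosome 1 at 7523341 to 7523776 (fold 16.8), and the strongest found only after knockdown on chromosome 10 at 135379960 to 135381022 (fold 13.4). Caki-1 control peaks were also absent from Caki-2 control (45.7%), RCC tissue (44.5%), RCC urine (41.5%) and normal urine (41.7%), all longer lists. They were absent from NAT tissue in 79.9% and from the Caki-2 knockdown in 59.3% of cases. Absence after knockdown therefore cannot be read as loss through knockdown alone.

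**Figure D4:**
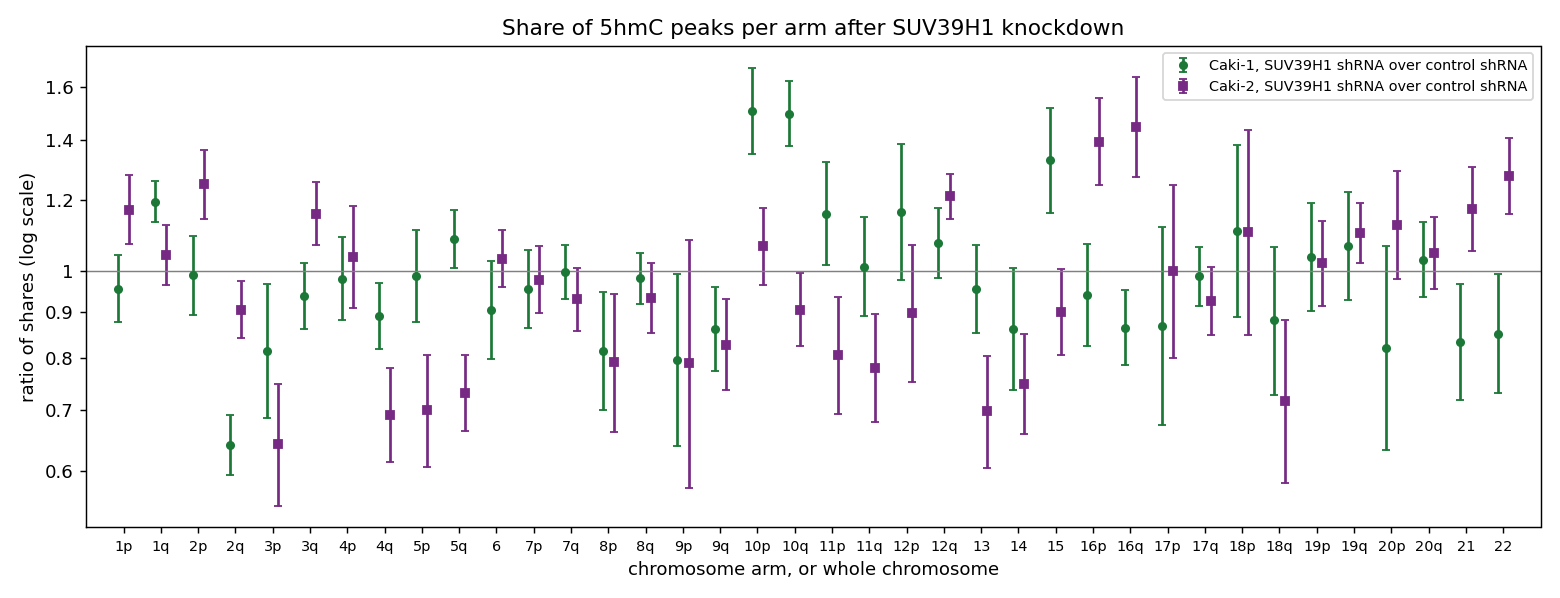
Ratio of the share of autosomal 5hmC peaks on each arm or whole chromosome (log axis), SUV39H1 shRNA over control shRNA, in Caki-1 (green circles) and Caki-2 (purple squares), with 95% exact intervals for counting error and 1 library per group. Both arms of chromosome 10 lie near 1.5 in Caki-1, and in Caki-2 16q lies at 1.45 and 3p at 0.642.

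In Caki-2 the list after knockdown was shorter by 6740 peaks, chromosomes 16 and 22 took larger shares and 3p, 4q and 13 smaller ones. The ratio of knockdown to control was 1.45 (95% interval 1.27 to 1.64) for 16q, 1.39 for 16p, 1.28 for chromosome 22, 1.25 for 2p and 1.21 for 12q. It was 0.642 (95% interval 0.549 to 0.750) for 3p, 0.692 for 4q and 0.698 for chromosome 13. Among 1 Mb windows the extremes were 27 to 28 Mb of chromosome 2, with 5 peaks in the control and 17 after knockdown (scaled log2 ratio 1.92), and 57 to 58 Mb of chromosome 17, with 24 and 3 (-2.31). The window at 39 to 40 Mb of chromosome 10 held 18 and 45 peaks (1.61), and that at 10 to 11 Mb of chromosome 21 held 10 and 20 (1.27). The last 2 windows were also the lowest in RCC against normal urine.

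Of the Caki-2 control peaks, 56.7% (95% interval 56.2 to 57.3%) were absent after knockdown, and 44.2% of the knockdown peaks (95% interval 43.6 to 44.8%) were absent from the control. Among control peaks with 16 or more summit fragments, 4.28% (95% interval 3.58 to 5.08%) were absent. The strongest absent peak, on chromosome 5 at 5352795 to 5353185 (fold 27.0), was found in all 6 libraries other than the Caki-2 knockdown. The strongest peak found only after knockdown lay on chromosome 7 at 1305078 to 1306504 (fold 15.8). Caki-2 control peaks were also absent from Caki-1 control (47.0%), RCC tissue (44.7%), RCC urine (42.3%) and normal urine (42.7%), all longer lists than the knockdown list. They were absent from NAT tissue in 79.8% and from the Caki-1 knockdown in 56.8% of cases. Absence after knockdown therefore cannot be read as loss through knockdown alone.

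The lines showed little agreement in regional differences after knockdown. Across 739 windows of 1 Mb the correlation between the log2 ratios of Caki-1 and Caki-2 was 0.0307, whereas neighbouring windows within a line had correlations of 0.406 in Caki-1 and 0.372 in Caki-2. Windows are not independent replicates. Among the windows named as extremes, that at 10 to 11 Mb of chromosome 21 rose from 12 to 49 peaks in Caki-1 and from 10 to 20 in Caki-2. That at 39 to 40 Mb of chromosome 10 rose from 37 to 57 and from 18 to 45. Both lie close to the widest gap between peaks of their chromosome and also differed between the urine pools. Of the 38 arms and whole chromosomes, 6 were higher and 9 lower in Caki-1 beyond their counting intervals, and 9 were higher and 13 lower in Caki-2. Lower in both lines were 5, against 3.08 expected if the lines were independent, 0 were higher in both against 1.42, and 6 went opposite ways against 4.18. Those lower in both were 2q (ratio 0.641 in Caki-1 and 0.906 in Caki-2), 3p (0.816 and 0.642), 4q (0.891 and 0.692), 8p (0.815 and 0.791) and 9q (0.862 and 0.829). In 1 Mb windows the standard deviation of the log2 ratio was 0.43 in Caki-1 and 0.49 in Caki-2, against 0.50 and 0.49 from simulated counting, which overstates the noise of lists that share peaks. Windows beyond 2-fold numbered 24 up and 16 down in Caki-1, with 26.6 and 28.7 from counting, and 34 up and 21 down in Caki-2, with 24.1 and 25.2. Among peaks found in both controls and at equal strength, peaks lost in Caki-1 were absent from the Caki-2 knockdown 20.2 percentage points more often than kept peaks. The same difference was 12.2 points in normal urine and 18.3 points in RCC urine, which had no knockdown.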

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

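None of the differences in this part was tested between the lines, and the test of list length and that of copy number on chromosome 10 were written down before their results were seen.

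In 6 of the 38 arms and whole chromosomes the share of peaks moved one way after SUV39H1 knockdown in Caki-1 and the opposite way in Caki-2, each beyond its counting interval. This compares with 4.18 expected if the lines were independent. A further 5 were lower in both lines and 0 were higher in both. Where the lines went opposite ways, the ratio of knockdown to control was 1.09 in Caki-1 and 0.732 in Caki-2 on 5q, 1.50 and 0.905 on 10q, and 1.16 and 0.806 on 11p. It was 0.865 and 1.45 on 16q, 0.835 and 1.17 on chromosome 21, and 0.852 and 1.28 on chromosome 22.

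The larger share of chromosome 10 after knockdown in Caki-1 was seen along the whole chromosome, though not to an equal extent. All 14 windows of 10 Mb had a ratio above 1, from 1.21 to 1.85, while Caki-2 as a whole was at 0.978 (95% interval 0.914 to 1.046). A difference in list length is argued against, since the ratio stayed at 1.46 with the same number of strongest peaks in both lists. A candidate explanation is more copies of chromosome 10 in the knockdown cells, which would also raise peaks found in both libraries. The median percentile of chromosome 10 among such peaks was 14.8 points higher in the knockdown list, at 60.6 against 45.7. An effect of SUV39H1 on this chromosome in Caki-1 alone stays open and was not tested, since copy number and knockdown fall on the same library.

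Signals also appeared in sequences that no comparison used. Mitochondrial DNA carried 8 peaks in Caki-1 control, 7 in Caki-1 knockdown, 9 in Caki-2 control, 7 in Caki-2 knockdown, 9 in RCC tissue, 6 in NAT tissue, 6 in RCC urine and 7 in normal urine. Unplaced and random contigs carried 90 peaks in Caki-1 control, 83 in Caki-1 knockdown, 91 in Caki-2 control, 98 in Caki-2 knockdown, 121 in RCC tissue, 157 in NAT tissue, 104 in RCC urine and 125 in normal urine.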

How the results depend on the processing

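The alternatives with 16 or more summit fragments, without the NAT library, with normal urine in place of NAT tissue, with 3p set against 3q, and every value of the difference between the urine pools were chosen after the data were examined. Of 52 alternatives over 9 results, 14 stayed within the main 95% interval, 36 moved outside it and 2 reversed. Shares are given in the order RCC tissue absent from NAT tissue, RCC urine absent from normal urine, control absent after knockdown in Caki-1 and in Caki-2, and Caki-1 control absent from Caki-2 control. With a -log10 q of at least 5 they were 79.6, 49.6, 53.0, 59.2 and 44.9%. With the same number of strongest peaks they were 80.9, 54.5, 46.1, 51.5 and 46.4%. With 50% of the peak covered they were 84.9, 55.7, 54.8, 60.0 and 48.1%. With peaks widened by 500 bp they were 79.7, 47.8, 49.1, 53.7 and 43.6%. With 16 or more summit fragments they fell to 12.4, 0.266, 1.78, 4.28 and 2.55%, so that these shares depend above all on weak peaks. RCC tissue peaks missing from NAT tissue were found in RCC urine in 37.0% of cases at the stricter q, 38.6% with the same number of peaks, 39.4% at 50% coverage, 44.5% with widened peaks and 47.5% without the NAT library. RCC tissue peaks were found in either line in 53.2, 54.9, 41.0 and 45.001% of cases under the first 4 of these settings. The difference between the urine pools, RCC minus normal, was -5.72 percentage points at the stricter q and -0.476 with the same number of peaks, where its interval (-1.04 to 0.0889) included 0. The 3p ratio reversed from 1.37 to 0.742 with normal urine in place of NAT tissue and to 0.747 for 3p relative to 3q, and the cause was not tested. NAT tissue over normal urine was at 0.541 on 3p but also at 0.552 on 3q, whereas RCC tissue was at 1.01 on 3q. A low 3p share against urine is thus not specific to RCC tissue, but one low relative to 3q was not seen in NAT tissue. The RCC to NAT ratio on 3p stayed between 1.307 and 1.408 under its other alternatives. Adding chromosome X moved no share outside its interval. No replicate could be left out, and no paired analysis was possible because each group had 1 library. The planned genomic context and gene list alternatives were not run, since no hg19 annotation was used here. At the inferred depth, peaks under 9 summit fragments were the least often found again, which limits every share of absent peaks.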

Other observations

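In this part the tests of depth, of the detection limit and of pericentromeric peaks were chosen only after their results were seen, and the strength groups of the test of lost sites were widened to all strengths after its first result was seen.

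Caki-2 carried a dense block of 5hmC peaks on chromosome 12, counted here between 72 and 86 Mb, a region singled out after its values were seen. Whether the region has more DNA copies in Caki-2 was not measured and cannot be told apart from a difference in 5hmC. The block went on beyond 86 Mb, as the window at 86 to 87 Mb held 50 peaks in Caki-2 control and 72 in Caki-2 knockdown. In Caki-1 that window held 5 and 3. The region from 72 to 86 Mb held 764 peaks in Caki-2 control (2.36% of the list) and 807 in Caki-2 knockdown (3.15%). In Caki-1 it held 72 peaks in the control (0.229%) and 74 after knockdown (0.286%), in RCC tissue 258 (0.458%), in NAT tissue 47 (0.102%), and in the urine pools 188 and 175. Neighbouring 1 Mb windows moved together between the control lines (correlation 0.841 over 907 pairs of windows) and between the tissues (0.674 over 1713), less so after knockdown in Caki-1 (0.406) and Caki-2 (0.372), and least between the urine pools (0.146 over 2289). The same windows of the lines after knockdown had a correlation of 0.0307 over 739.

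NAT tissue peaks were clustered as well as terminal. Of them 40.03% lay within 5 kb of the next peak, against 15.0% in RCC tissue, 16.6% in RCC urine and 19.7% in normal urine. Strong summits were fewer in NAT tissue, with 941 peaks of 16 or more fragments against 2968 in RCC tissue, but the median summit was not lower, at 7 against 6 fragments.

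Among NAT tissue peaks 34248 (74.1%) overlapped no peak of any other library. Lower depth at peak calling is argued against by a background per kb 1.00 times that of RCC tissue, which does not speak to the reads originally sequenced. Wide or displaced peaks are argued against by the 25.3% of NAT peaks that overlapped RCC tissue peaks after widening by 500 bp, with 5.53% for shifted peaks. At 9 to 11 summit fragments absence from normal urine was 51.9 percentage points higher in NAT than in RCC tissue, at 77.9% against 26.0%. Weak peaks alone are argued against by this gap, although equal fragments stood over a higher background per position in NAT tissue. Chromosome ends alone are argued against too, as only 26.3% of the NAT peaks farther than 5 Mb from an end were found in normal urine, compared with 48.8% in RCC tissue. A difference in capture or in the GC content of the captured DNA was not tested and stays open beside a difference of the tissue itself, since both fall on 1 library.

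Both lines had fewer peaks after SUV39H1 knockdown, and fewer strong ones, with 1704 of 16 or more summit fragments against 3142 in Caki-1 and 1034 against 2965 in Caki-2. Unequal depth at peak calling is argued against by background ratios of 1.00 in both lines. All 8 libraries had the same inferred background, so this does not speak to the number of reads originally sequenced. Weaker capture in the knockdown libraries was not tested and stays open. Loss of the same sites could not be decided. At equal strength, peaks lost in Caki-1 were absent from the Caki-2 knockdown 20.2 percentage points more often than kept peaks. The same difference was 7.96 points less in normal urine, but 18.3 points in RCC urine, so nearly all of it was also present in a library with no knockdown.

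The hypothesis that SUV39H1 knockdown may raise 5hmC at pericentromeric DNA, where H3K9me3 is abundant, was tested only on peaks beside the centromere gaps, within 2 Mb. Their share relative to control was 1.01 times in Caki-1 (95% interval 0.909 to 1.12) and 1.16 times in Caki-2 (95% interval 1.049 to 1.28), while the urine pools differed 1.03-fold. Without chromosome 10 the ratios were 0.911 and 1.03, so the higher share in Caki-2 rested on that chromosome. An effect in both lines was not shown on the chromosomes used, and a small one in Caki-1 was not excluded by its interval. The window at 10 to 11 Mb of chromosome 21, close to that chromosome's widest gap between peaks, was not counted here. It rose from 12 to 49 peaks in Caki-1 and from 10 to 20 in Caki-2. Without any knockdown, it held 14 peaks in RCC urine and 47 in normal urine.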
